A study of Homo sapiens with 9 samples.

How the data were processed

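RNA sequencing was done on 9 libraries of A549 cells, a human lung adenocarcinoma cell line: 3 of the control CK, 3 of treatment P and 3 of treatment Y. Per the labels, the libraries were made with the NEBNext Ultra RNA kit and read on an Illumina instrument as paired reads of 150 bases, and the submitters' processing notes name the build GRCh38. The aligner, the tool that estimated the levels and the annotation release were not given in the sources used here. Neither was the way mRNA was selected from total RNA. The codes P and Y are not expanded in the labels, and no dose or duration is given.

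The deposited values are FPKM, fragment counts scaled for transcript length and library depth, as the authors computed them, with 1 value per gene and library repeated on each transcript of the gene. The table holds 83739 transcripts of 19793 genes, of which 19730 are protein-coding and 13 are encoded in mitochondrial DNA, and it pairs each gene ID with a symbol and a position. A symbol was shared by more than 1 gene ID in 15 cases, so genes were handled by ID. All per-sample columns matched a library, and the deposited group means differed from the means of the 3 columns by no more than 1e-6 FPKM. The deposited table also carries other values, namely the authors' own log2 fold change and adjusted p for each comparison and the transcript length in bases. The authors' test was not named.

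The table analysed holds FPKM and no read counts, so the test intended for counts was replaced by its fallback, fixed before the data were examined. The sequencing depth could only be estimated, from the smallest steps of FPKM times transcript length in genes with a lone transcript. The steps implied 24500000 to 28600000 fragments per library, at which 1 FPKM on a transcript of 2000 bases equals 48.9 to 57.2 fragments. Between 31.7% and 34.3% of the low values were whole multiples of the step within a tolerance of 0.02. Fragment counts were therefore not recovered, and no counting intervals are given.

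FPKM values were transformed to log2(FPKM + 1) and fitted with limma-trend (limma 3.58.1, R 4.3.3) over all 9 libraries with group as the factor and no block. Genes with at least 1 FPKM in at least 3 libraries were tested, 11958 in all. The tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p under 0.05 were called. Log2 fold changes refer to log2(FPKM + 1), which understates the change of genes near or below 1 FPKM. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.

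The 3 comparisons were P against CK, Y against CK and Y against P. Before the data were examined, 29 gene lists were fixed, of which 3 hold markers of other cell types. The 26 lists with at least 5 tested members were tested with camera from limma at its preset correlation of 0.01, and again with the correlation estimated per list. Members were counted by the gene test, over all genes tested and adjusted over the list alone. The rule for named genes was also fixed then. It took the 12 genes with the largest rise and the 12 with the largest fall in each comparison with CK, and 6 each way for Y against P. These genes had to be called, to average at least 1 FPKM and to have all 3 libraries of a group above all 3 of the other. Up to 4 members of each list with the smallest adjusted p were added, as was a fixed set of xenobiotic and hormone response genes. Not every gene that the rule took is reported here. The effects of P and Y were correlated across genes and set beside 100 simulations of unchanged groups that share their 3 controls.

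The alternatives chosen before the data were examined were no filter on low values, a threshold on the fold change, the 6 compared libraries alone, a replicate block, a pseudocount of 0.1, protein-coding genes alone, estimated list correlations and leaving out each library in turn. A filter at 5 FPKM, median-ratio scaling, rescaling of the nuclear genes to equal totals, and a split of the controls so that none served both comparisons were added after seeing the data. The test was checked on simulated data with the number of genes and the spread of the comparison of P with CK, in which 67, 67 and 66 genes were changed by 0.5, 1 and 2 on the log2 scale, far fewer than were called in the real comparison. It recovered 28.4%, 95.5% and 100% of them, and 5.10% of its calls were false. A planted list passed and none of the other lists did, on genes simulated as independent. Term enrichment was left out because the table pairs genes with protein domain descriptions and not with pathway terms.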

Results

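A549 cells, a human lung adenocarcinoma cell line, were profiled by RNA sequencing under control CK, treatment P and treatment Y, with 3 libraries per group. The series title names hormone-like pollutants from biomass combustion, and its design calls the libraries biological replicates. Neither code is expanded in the labels. Implied depth was 25600000 ± 679000 fragments (SD, n = 3) in CK, 27700000 ± 1010000 in P and 25100000 ± 827000 in Y. The summed FPKM was 321916 ± 15937 in CK, 274932 ± 6751 in P and 272072 ± 11270 in Y. Mitochondrially encoded mRNAs made up 3.09 ± 0.123% of it in CK, 0.783 ± 0.0176% in P and 1.53 ± 0.350% in Y. All values below are FPKM means ± SD with n = 3, positions are on GRCh38, and adjusted p-values come from limma with Benjamini-Hochberg correction.

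The comparison of P with CK asked which genes responded to treatment P, with the series title pointing to genes of xenobiotic and hormone response. CYP1B1 (ENSG00000138061, chromosome 2, 38067509 to 38109902), a monooxygenase induced through the aryl hydrocarbon receptor, rose from 16.9 ± 1.07 to 101 ± 11.8 (log2 fold change 2.51, SE 0.10, adjusted p = 4.79e-08). CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725536), the classic target of the same receptor, rose from 0.0745 ± 0.0417, a level below the filter of 1 FPKM, to 1.42 ± 0.115 (1.17, SE 0.16, adjusted p = 1.70e-04). HMOX1, the haem-degrading enzyme of oxidative stress, rose from 39.4 ± 3.38 to 304 ± 23.9 (2.92, SE 0.10, adjusted p = 3.45e-08). NQO1, a quinone reductase that NRF2 and the aryl hydrocarbon receptor induce, fell from 532 ± 70.8 to 171 ± 24.0 (-1.63, SE 0.14, adjusted p = 8.24e-06). All 3 P libraries lay on the same side of all 3 controls for each of these genes.

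Of the 10 tested aryl hydrocarbon receptor targets, where 2 gene IDs carry the symbol AHRR, 6 rose and 3 fell in P. XDH rose from 0.421 ± 0.0649 to 4.10 ± 0.484 and TIPARP from 24.2 ± 2.94 to 140 ± 39.2, while ALDH3A1, an aldehyde dehydrogenase, fell from 603 ± 79.3 to 81.8 ± 11.97 (-2.87, SE 0.13, adjusted p = 1.26e-07). The list as a whole did not pass (camera adjusted p = 0.425). Among 22 NRF2 antioxidant targets 8 rose and 12 fell. AKR1B10, a reductase of the list, fell from 1409 ± 149 to 381 ± 61.0, and the list did not pass (adjusted p = 0.237). The counts were equal when adjusted over the list alone.

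Hormone receptor genes were also covered. NR3C1, the glucocorticoid receptor, fell from 50.3 ± 9.07 to 21.8 ± 5.65 (-1.18, SE 0.19, adjusted p = 5.34e-04). FKBP5, a glucocorticoid-induced chaperone, fell from 3.28 ± 0.120 to 1.69 ± 0.168 (-0.67, SE 0.09, adjusted p = 2.24e-04). TSC22D3, induced by the same receptor, was 5.17 ± 0.216 in CK and 4.29 ± 1.17 in P (-0.25, SE 0.21, adjusted p = 0.364). AHR itself rose from 26.6 ± 0.706 to 38.3 ± 1.74 (0.51, SE 0.08, adjusted p = 5.66e-04), at a locus where another annotated gene overlaps on the same strand. ESR1 and PGR, the estrogen and progesterone receptors, reached at most 0.0202 and 0.0149 FPKM in any library, and ESR2 at most 0.540, all below the filter.

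The hormone lists reported here did not pass in P. Of 15 glucocorticoid receptor targets 6 rose, among them DUSP1, and 7 fell, among them PDK4 (camera adjusted p = 0.838), and 6 rose and 3 fell with equal nuclear totals. The median of that list was -0.25, its mean 0.13, and its test pointed down. Of 10 estrogen receptor targets 4 rose and 4 fell (adjusted p = 0.984), with a median of 0.10 and a test that pointed down. Of 19 nuclear receptor genes 7 rose and 5 fell (adjusted p = 0.654), and of 13 genes of steroid hormone metabolism 3 rose and 5 fell (adjusted p = 0.425). The counts of these lists were equal when adjusted over the list alone. The last list had a median of -0.10, which turned to 0.09 after rescaling nuclear genes to equal totals.

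**Figure D1:**
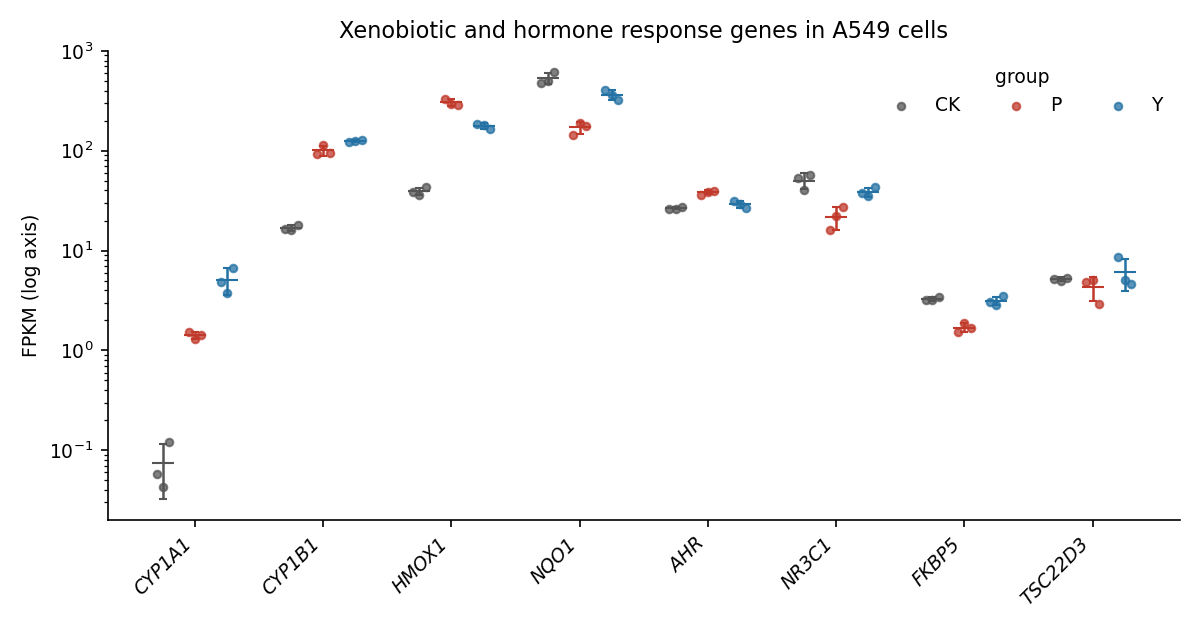
FPKM (log axis) of fixed xenobiotic and hormone response genes above the filter, with points for libraries, horizontal lines for group means and bars for the SD (n = 3). CYP1B1 lies at 16.9 in CK, 101 in P and 125 in Y, and CYP1A1 at 0.0745, 1.42 and 5.10.

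Across the genome, the largest rise in P on the log2(FPKM + 1) scale was that of GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176), a stress-induced cytokine and p53 target, from 17.0 ± 2.70 to 333 ± 21.4 (log2 fold change 4.22, SE 0.11, adjusted p = 1.90e-08). DUSP5 and DUSP1, phosphatases of MAP kinases, rose from 9.49 ± 0.489 to 181 ± 8.23 and from 19.6 ± 0.450 to 200 ± 25.9. The lipid droplet coat gene PLIN2 rose from 18.5 ± 2.08 to 288 ± 22.8, and the BMP antagonist GREM1 from 0.576 ± 0.177 to 25.2 ± 2.30, whose ratio of means, 43.6, exceeded the 19.6 of GDF15. PHLDA1 reached 49.3 ± 30.7, with 14.0 in P replicate 3. UPP1, STC2, FAM129A and BEX2 completed the 12 largest rises on that scale with TRIB3 and PPP1R15A, and the log2 fold changes of all 12 lay between 3.21 and 4.22.

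The largest fall in P on that scale was that of CPLX2 (ENSG00000145920, chromosome 5, 175796310 to 175884021), a regulator of vesicle release, from 67.0 ± 27.4 to 0.591 ± 0.148 (-5.35, SE 0.25, adjusted p = 1.81e-07). Without CK replicate 1 the log2 fold change of CPLX2 was -5.04, and that of FGA with all libraries was also -5.04. The fibrinogen chains FGA, FGB and FGG fell from 52.0 ± 4.27, 34.8 ± 7.26 and 42.0 ± 3.80 to 0.623 ± 0.272, 1.05 ± 0.490 and 1.63 ± 0.358. CLDN2, a tight junction claudin, fell from 24.1 ± 0.487 to 0.223 ± 0.0227, and the chemokine CCL2 from 35.1 ± 1.32 to 1.19 ± 0.350. Clustered histone genes filled 5 of the 12 places, and HIST1H3J among them fell from 729 ± 101 to 29.2 ± 3.40. Histone copies are nearly identical, so their reads are hard to assign to a copy.

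Gene lists of cell division fell in P. All 20 tested mitosis genes fell (median log2 fold change -2.49, camera adjusted p = 6.34e-16), and so did all 23 tested DNA replication genes (median -1.65, adjusted p = 6.82e-15). With an estimated correlation both gave adjusted p = 0.234. KIF20A, a mitotic kinesin, fell from 23.1 ± 0.954 to 1.07 ± 0.261 (-3.55, SE 0.10, adjusted p = 1.90e-08) and TOP2A, a DNA topoisomerase, from 180 ± 11.4 to 15.5 ± 2.93. MCM7 of the replicative helicase fell from 58.1 ± 2.82 to 16.4 ± 1.84. Counts adjusted over the list alone were also 20 and 23.

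Lists of mitochondrial respiration pointed down in P. All 13 mitochondrially encoded mRNAs fell (median -2.13, camera adjusted p = 1.43e-10, and adjusted p = 0.234 with an estimated correlation). MT-ND3, a subunit of complex I, fell from 125 ± 2.50 to 5.01 ± 1.32 (-4.41, SE 0.16, adjusted p = 3.89e-08), and MT-CO2, of cytochrome oxidase, from 1571 ± 68.8 to 156 ± 6.06. Among 23 nuclear-encoded genes of oxidative phosphorylation 15 fell and none rose (median -0.51, adjusted p = 5.03e-05, and adjusted p = 0.234 with an estimated correlation). NDUFB3 among them fell from 127 ± 10.5 to 44.5 ± 5.80. The counts adjusted over the list alone were 13 and 15. The medians of both lists were negative under both other scalings, and with equal nuclear totals the nuclear-encoded one was -0.32, with 12 falls.

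**Figure D2:**
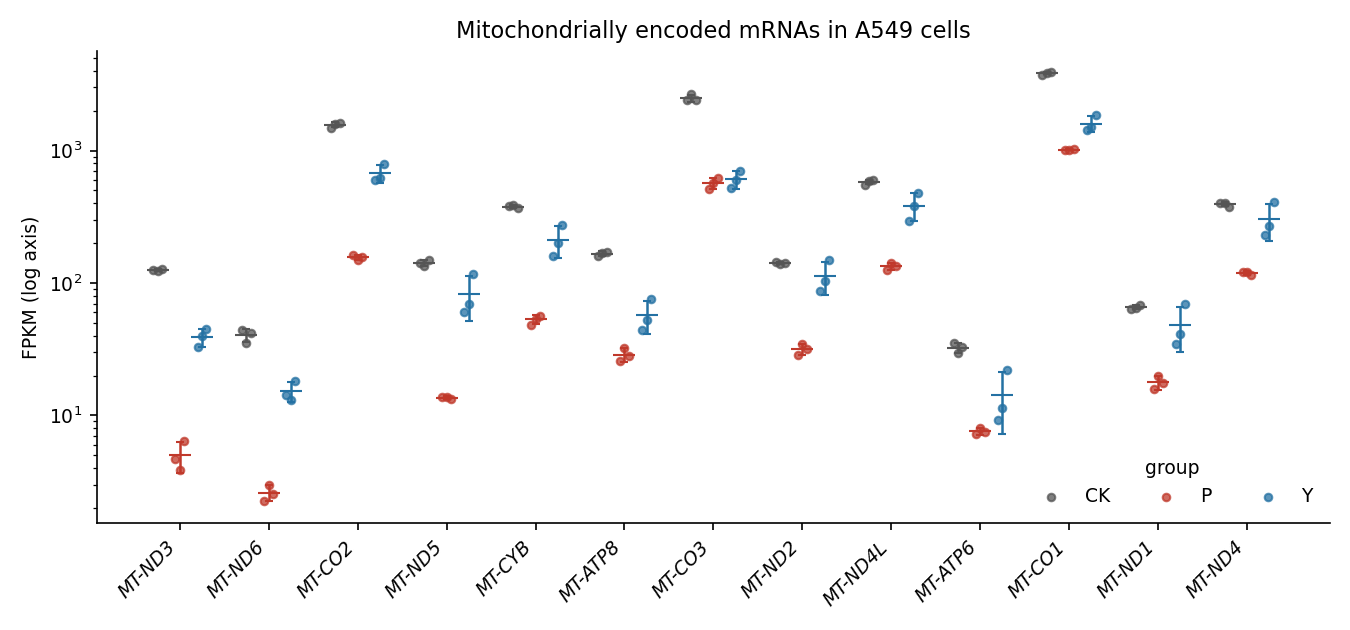
FPKM (log axis) of the 13 mitochondrially encoded mRNAs in CK, P and Y, with points for libraries, horizontal lines for group means and bars for the SD (n = 3). MT-ND3 lies at 125 in CK, 5.01 in P and 39.1 in Y, and the P libraries lie below the CK libraries for all 13 genes.

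Stress and signalling lists pointed up in P. Of 19 genes of the ATF4 amino acid response 17 rose and none fell (median 1.49, camera adjusted p = 8.23e-09, and adjusted p = 0.234 with an estimated correlation). TRIB3, a pseudokinase, rose from 15.8 ± 1.25 to 234 ± 5.92 (3.81, SE 0.08, adjusted p = 4.21e-09), and PPP1R15A, a phosphatase subunit acting on the translation factor eIF2, from 3.54 ± 0.539 to 50.6 ± 7.10. Among 15 immediate early genes 11 rose, with JUN from 4.61 ± 0.392 to 34.8 ± 2.07, and 1, JUNB, fell (median 1.32, adjusted p = 6.93e-05, and adjusted p = 0.234 with an estimated correlation). Of 21 NF-kB inflammatory genes 14 rose, with PTGS2, the inducible cyclooxygenase, from 85.6 ± 3.28 to 450 ± 16.6, and 4 fell, CCL2 among them (median 1.37, adjusted p = 0.00173, and adjusted p = 0.234 with an estimated correlation). Adjusted over the list alone, 17, 12 and 14 rose and 0, 1 and 5 fell, and 2 NF-kB genes fell with equal nuclear totals.

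Further lists passed by less in P. Of 15 genes of the unfolded protein response 8 rose, with HSPA5, the chaperone BiP, from 33.0 ± 3.35 to 121 ± 8.64, and 3 fell (median 0.47, camera adjusted p = 0.0376, and adjusted p = 0.234 with an estimated correlation). Of 20 p53 targets 10 rose, with MDM2 from 19.0 ± 1.66 to 39.0 ± 3.01, and 1, FDXR, fell (median 0.33, adjusted p = 0.0376, and adjusted p = 0.458 with an estimated correlation). Of 21 hypoxia and glycolysis genes 4 rose and 10 fell, with LDHA, lactate dehydrogenase, from 368 ± 22.7 to 79.4 ± 9.96 (median -0.29, adjusted p = 0.0492, and adjusted p = 0.458 with an estimated correlation). Adjusted over the list alone, 9, 10 and 4 rose and 3, 1 and 10 fell. Without CK replicate 1 the calls ended for all 3 lists, at adjusted p = 0.0631 for the unfolded protein response and p53 targets and 0.156 for hypoxia. The hypoxia call also ended without any other library except P replicate 2, at adjusted p-values from 0.0502 to 0.0771, and with median-ratio scaling at 0.0675. With equal nuclear totals 11 genes of the unfolded protein response rose and 0 fell, 11 p53 targets rose and 0 fell, and the hypoxia median was -0.11, with 5 rises and 7 falls.

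The other lists did not pass in P. Keratins KRT8 and KRT18 fell from 1694 ± 223 to 221 ± 9.88 and from 662 ± 74.0 to 146 ± 11.9, while 3 rose and 6 fell of the 12 epithelial genes (camera adjusted p = 0.195). Among 18 mesenchymal genes 6 rose, with VIM from 194 ± 16.0 to 531 ± 47.3, and 8 fell (adjusted p = 0.425). Of 23 cholesterol synthesis genes 8 rose and 4 fell (0.350), and of 13 PPAR and fatty acid oxidation genes 4 rose and 2 fell (0.425). Interferon-stimulated genes gave 4 rises and 8 falls of 15 (0.0859), heat shock proteins 1 and 6 of 11 (0.0633), and surfactant and secretory genes 1 and 4 of 8 (0.0545). Metallothionein and zinc genes gave 2 rises and 3 falls of 7 (0.294), and cytosolic ribosomal proteins 1 and 2 of 28 (0.708). Adjusted over the list alone, the ribosomal counts were 0 and 0, and 7 mesenchymal genes rose, with the other counts equal. With equal nuclear totals 9 ribosomal protein genes rose and 0 fell, 13 cholesterol genes and 7 PPAR genes rose, 3 heat shock genes fell, and 7 mesenchymal genes rose and 7 fell.

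In total, 3464 genes were higher and 2780 lower in P than in CK, of 11958 tested, and 656 and 754 of them differed by at least 1 on the log2 scale. In 7368 genes the 3 libraries of P and CK did not overlap, where chance gives 10%. Of the calls 55.5% were rises, and after rescaling nuclear genes to equal totals 70.7% were, with 4781 higher and 1980 lower, since that scaling moved the median of all genes from 0.06 to 0.22. Median-ratio scaling gave 50.1% rises, with 3188 higher and 3171 lower. Of 26 lists tested 10 passed, and with an estimated correlation none did by camera, 4 having an unadjusted p under 0.05.

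The comparison of Y with CK asked the same question of treatment Y. CYP1B1 rose from 16.9 ± 1.07 to 125 ± 3.25 (log2 fold change 2.82, SE 0.10, adjusted p = 1.50e-07) and CYP1A1 from 0.0745 ± 0.0417 to 5.10 ± 1.52 (2.48, SE 0.16, adjusted p = 2.35e-06). HMOX1 rose from 39.4 ± 3.38 to 177 ± 10.5 (2.14, SE 0.10, adjusted p = 3.47e-07), and NQO1 fell from 532 ± 70.8 to 362 ± 42.0 (-0.55, SE 0.14, adjusted p = 0.0106). All 3 Y libraries lay on the same side of all 3 controls for these genes. Of 10 aryl hydrocarbon receptor targets 4 rose and 3 fell, and the list did not pass (median 0.42, camera adjusted p = 0.211). Of 22 NRF2 targets 5 rose and 10 fell (adjusted p = 0.312), and 6 and 11 adjusted over the list alone. With equal nuclear totals 7 NRF2 targets rose and 6 fell.

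Hormone receptor genes were measured in Y as well. NR3C1 was 50.3 ± 9.07 in CK and 38.5 ± 4.05 in Y (-0.36, SE 0.19, adjusted p = 0.149). FKBP5 was 3.28 ± 0.120 and 3.15 ± 0.312 (-0.05, SE 0.09, adjusted p = 0.711), and its sign turned to 0.12 after rescaling nuclear genes to equal totals. TSC22D3 was 5.17 ± 0.216 and 6.11 ± 2.17 (0.16, SE 0.21, adjusted p = 0.575), and -0.075 without Y replicate 1. AHR was 26.6 ± 0.706 and 29.1 ± 2.28 (0.12, SE 0.08, adjusted p = 0.262), and passed at 0.33 with equal nuclear totals (adjusted p = 0.00271). Glucocorticoid and estrogen receptor targets gave camera adjusted p-values of 0.806 and 0.454, nuclear receptors 0.231 and steroid hormone metabolism 0.252. The glucocorticoid list had a positive median, 0.03, which median-ratio scaling turned to -0.0036, and a test that pointed down.

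GDF15 again had the largest rise on the log2(FPKM + 1) scale, to 336 ± 17.8 from 17.0 ± 2.70 (4.23, SE 0.11, adjusted p = 3.40e-08). Its ratio of means, 19.7, was below those of NGFR (100) and CYP1A1 (68.5). NGFR, a neurotrophin receptor, rose from 0.116 ± 0.0513 to 11.7 ± 1.70, and TRIB3 from 15.8 ± 1.25 to 154 ± 4.74. DDIT3, the stress transcription factor CHOP, whose locus overlaps another annotated gene, rose from 2.12 ± 0.623 to 19.0 ± 3.39. PHLDA1, CHAC1, BEX2, FAM129A and ARG2 were also among the 12 largest rises. So was the histone gene HIST2H4B (2.61, SE 0.89, adjusted p = 0.0383), whose call ended on leaving out any CK or Y library, at adjusted p-values from 0.0647 to 0.112, and at 0.0789 with no filter on low values.

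The largest fall in Y on that scale was that of DKK1 (ENSG00000107984, chromosome 10, 52314281 to 52317657), a secreted Wnt antagonist, from 343 ± 27.4 to 13.7 ± 2.06 (-4.55, SE 0.12, adjusted p = 3.40e-08). CLDN2 fell from 24.1 ± 0.487 to 0.745 ± 1.25 (-4.07), with 2.19 in Y replicate 1 and a log2 fold change of -4.62 without that library, past that of DKK1. CPLX2 fell from 67.0 ± 27.4 to 4.15 ± 1.07 and CCL2 from 35.1 ± 1.32 to 2.40 ± 0.311. Histone genes filled 7 of the 12 places, with HIST1H2AH from 1273 ± 150 to 136 ± 18.0.

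Lists of cell division and respiration pointed down in Y as well. All 20 mitosis genes fell (median -2.06, camera adjusted p = 1.17e-17, and adjusted p = 0.201 with an estimated correlation), with MKI67, the proliferation antigen, from 16.8 ± 0.715 to 2.07 ± 0.272. All 23 DNA replication genes fell (median -1.53, adjusted p = 2.91e-16, and adjusted p = 0.198 with an estimated correlation), with FEN1, a flap endonuclease, from 20.3 ± 2.28 to 4.04 ± 0.213. Of the 13 mitochondrially encoded mRNAs 10 fell (median -1.23, adjusted p = 2.26e-06, and adjusted p = 0.294 with an estimated correlation), with MT-CO1 from 3832 ± 75.1 to 1598 ± 223. Among 23 nuclear-encoded oxidative phosphorylation genes 1 rose and 9 fell (median -0.25, adjusted p = 0.00587, and adjusted p = 0.292 with an estimated correlation). Of 21 hypoxia and glycolysis genes 2 rose and 9 fell (median -0.41, adjusted p = 0.00659, and adjusted p = 0.292 with an estimated correlation), with ENO1, enolase, from 523 ± 13.4 to 216 ± 7.94. Adjusted over the list alone, 20, 23, 12, 9 and 9 fell and 0, 0, 0, 1 and 3 rose. With equal nuclear totals 6 nuclear-encoded oxidative phosphorylation genes fell (median -0.04) and 5 hypoxia genes (median -0.19).

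Stress lists pointed up in Y. Of 19 genes of the ATF4 response 16 rose and none fell (median 1.46, camera adjusted p = 2.18e-10, and adjusted p = 0.198 with an estimated correlation), with PSAT1, of serine synthesis, from 23.9 ± 3.19 to 69.6 ± 4.97. Of 20 p53 targets 14 rose and none fell (median 0.59, adjusted p = 7.77e-05, and adjusted p = 0.226 with an estimated correlation), with MDM2 from 19.0 ± 1.66 to 46.5 ± 2.95. Of 15 immediate early genes 10 rose and 2 fell (median 0.83, adjusted p = 0.00244, and adjusted p = 0.292 with an estimated correlation), with IER3 from 28.2 ± 5.05 to 102 ± 9.52. The rises adjusted over the list alone numbered 18, 15 and 10. Among 21 NF-kB genes 9 rose and 8 fell, and the list did not pass (median 0.17, mean -0.04, a test that pointed up, adjusted p = 0.834).

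Lists of epithelial and mesenchymal genes pointed down in Y. Of 12 epithelial junction and keratin genes 8 fell, with KRT8 from 1694 ± 223 to 372 ± 35.03, and 1, OCLN, rose (median -0.70, camera adjusted p = 9.73e-04, and adjusted p = 0.198 with an estimated correlation). Of 18 mesenchymal genes 10 fell, with FN1, fibronectin, from 481 ± 20.9 to 273 ± 14.7 and TGFB2 from 8.15 ± 0.792 to 1.64 ± 0.162, and 1, ZEB1, rose (median -0.56, adjusted p = 0.00587, and adjusted p = 0.292 with an estimated correlation). The falls adjusted over the list alone numbered 9 and 10. With equal nuclear totals 4 mesenchymal genes rose and 9 fell. The lists of unfolded protein response (0.0803), interferon-stimulated genes (0.0575), surfactant and secretory genes (0.0723) and metallothionein and zinc genes (0.0723) came closest among those that did not pass.

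**Figure D3:**
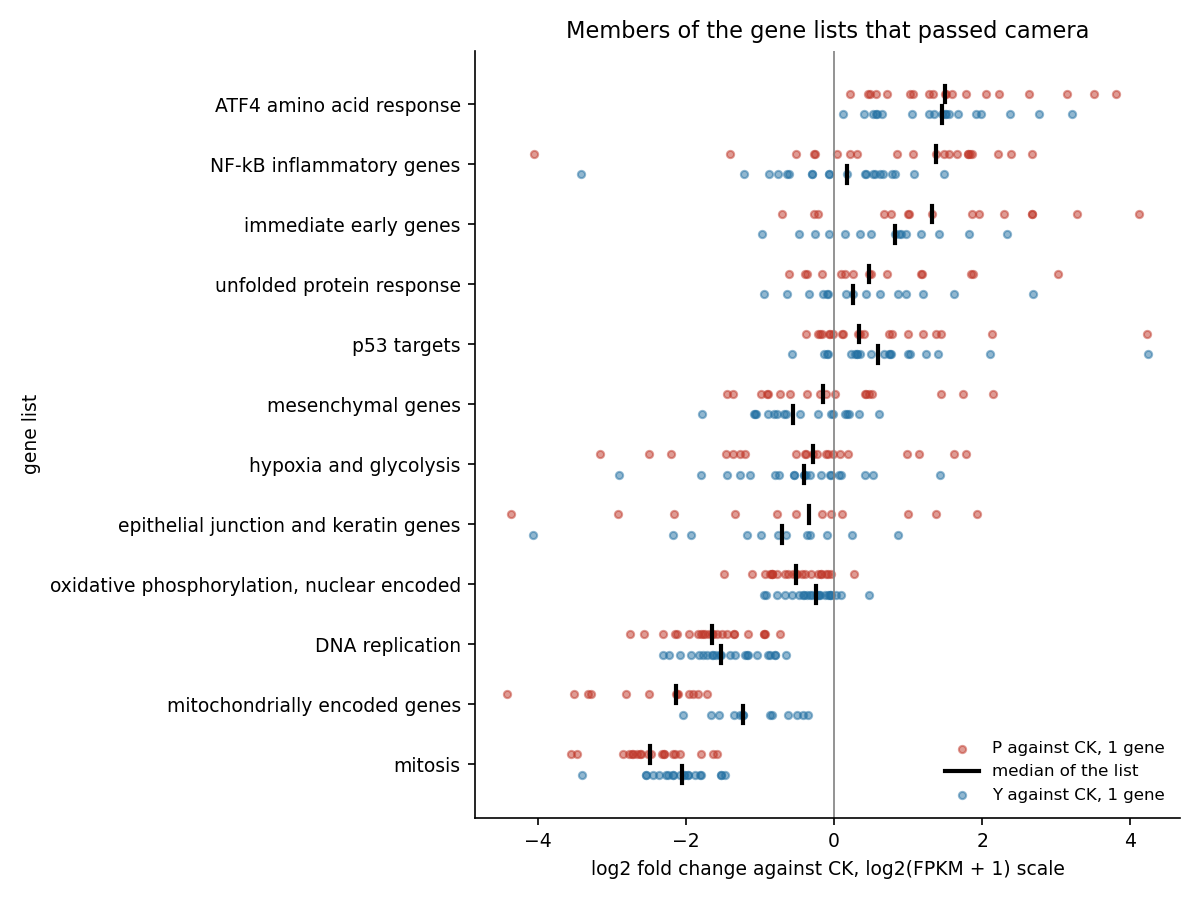
Log2 fold change against CK of each tested member of the lists that passed in P or Y, with points for genes and bars for list medians. The median of mitosis is -2.49 in P and -2.06 in Y, and that of NF-kB genes 1.37 in P and 0.17 in Y.

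In total, 2651 genes were higher and 2432 lower in Y than in CK, and 271 and 560 of them differed by at least 1 on the log2 scale. In 6240 genes the libraries of Y and CK did not overlap, where chance gives 10%. Rises made up 52.2% of the calls, and 74.3% after rescaling nuclear genes to equal totals (4493 higher and 1551 lower), which moved the median of all genes from 0.04 to 0.22. Falls outnumbered rises with median-ratio scaling (2501 higher and 2712 lower, 48.0% rises), with the filter at 5 FPKM (49.7% rises), and without CK replicate 1, Y replicate 1 or Y replicate 3 (49.9%, 49.1% and 49.5%). Of 26 lists 10 passed, and with an estimated correlation none did by camera, 5 having an unadjusted p under 0.05.

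The comparison of Y with P tested where the treatments differed. MMP1 (ENSG00000196611, chromosome 11, 102789919 to 102798160), interstitial collagenase, was lower in Y, at 0.703 ± 0.117 against 9.69 ± 0.820 in P (log2 fold change -2.65, SE 0.09, adjusted p = 5.40e-07). HMGA2, a chromatin protein, was 7.94 ± 0.559 in Y and 52.1 ± 1.82 in P (-2.57, SE 0.08, adjusted p = 3.83e-07). GREM1 and KLF6 were also lower in Y, as was the read-through gene ARPIN-AP3S2. Higher in Y were the fibrinogen chain FGA, at 7.84 ± 0.316 against 0.623 ± 0.272, TNFSF15, at 4.90 ± 0.584 against 0.182 ± 0.0666, and the prostaglandin dehydrogenase HPGD, at 38.3 ± 4.14 against 6.97 ± 1.46. ZBED6, which lies within ZC3H11A, was higher too.

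Xenobiotic genes differed in opposite directions. CYP1A1 was higher in Y, at 5.10 ± 1.52 against 1.42 ± 0.115 (1.31, SE 0.16, adjusted p = 3.43e-04), as were ALDH3A1 (2.16, SE 0.13, adjusted p = 6.61e-06) and NQO1 (1.08, SE 0.14, adjusted p = 5.44e-04). HMOX1 was lower in Y, at 177 ± 10.5 against 304 ± 23.9 (-0.77, SE 0.10, adjusted p = 4.04e-04), and so were XDH (-1.77, SE 0.10, adjusted p = 5.18e-06) and AHR (-0.39, SE 0.08, adjusted p = 0.00806). NR3C1 (0.82, SE 0.19, adjusted p = 0.0123) and FKBP5 (0.62, SE 0.09, adjusted p = 0.00126) were higher in Y. The difference in CYP1B1 (0.32, SE 0.10, adjusted p = 0.0385) lost its call without CK replicate 1 or 2, P replicate 1 or 3, or any Y library, at adjusted p-values from 0.0507 to 0.139, and with the 6 compared libraries alone at 0.0630. TSC22D3 (0.41, adjusted p = 0.206) did not pass. Of 10 aryl hydrocarbon receptor targets 5 were higher and 1 lower in Y (camera adjusted p = 0.0998).

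Inflammatory and early response lists pointed down in Y against P. Of 21 NF-kB genes 17 were lower and 2 higher (median -0.90, camera adjusted p = 1.42e-09, and adjusted p = 0.160 with an estimated correlation), with the chemokines CCL20 at 5.21 ± 0.337 against 18.1 ± 0.436 and CXCL2 at 27.1 ± 1.74 against 102 ± 12.7. Of 15 immediate early genes 9 were lower (median -0.85, adjusted p = 9.24e-05, and adjusted p = 0.581 with an estimated correlation), with DUSP5 at 52.0 ± 1.66 against 181 ± 8.23. Of 23 cholesterol synthesis genes 10 were lower and 2 higher (median -0.33, adjusted p = 0.00142, and adjusted p = 0.591 with an estimated correlation), with HMGCS1 at 12.8 ± 0.557 against 21.6 ± 1.31. Of 18 mesenchymal genes 8 were lower (median -0.30, adjusted p = 0.00640, and adjusted p = 0.591 with an estimated correlation), with VIM at 188 ± 6.45 against 531 ± 47.3. Adjusted over the list alone, 17, 9, 14 and 8 were lower and 3, 0, 2 and 1 higher.

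Mitochondrial and cell division lists pointed up in Y against P. Of the 13 mitochondrially encoded mRNAs 11 were higher (median 1.49, camera adjusted p = 7.91e-12, and adjusted p = 0.581 with an estimated correlation), with MT-ND3 at 39.1 ± 6.05 against 5.01 ± 1.32 and MT-ND5 at 82.1 ± 30.1 against 13.6 ± 0.294. The mitochondrial share of summed FPKM was 1.93% in Y replicate 3 against 1.27% and 1.39% in Y replicates 1 and 2, and without replicate 3 the median was 1.32. Of 23 nuclear-encoded oxidative phosphorylation genes 4 were higher (median 0.18, adjusted p = 0.00142, and adjusted p = 0.586 with an estimated correlation), with NDUFV2 at 136 ± 9.52 against 81.8 ± 7.37. Of 20 mitosis genes 7 were higher (median 0.32, adjusted p = 1.53e-04, and adjusted p = 0.605 with an estimated correlation), with TOP2A at 32.4 ± 1.67 against 15.5 ± 2.93, and 11 were higher with median-ratio scaling. Of 23 DNA replication genes 4 were higher, with PCNA at 135 ± 17.9 against 69.4 ± 4.93 (median 0.13, adjusted p = 0.0151, and adjusted p = 0.618 with an estimated correlation), and without P replicate 3 this list gave 0.122. The counts adjusted over the list alone were 12, 3, 12 and 4.

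In total, 1160 genes were higher and 1577 lower in Y than in P, and 91 and 236 of them differed by at least 1 on the log2 scale. In 4680 genes the libraries of Y and P did not overlap, where chance gives 10%. The higher genes numbered 702 without Y replicate 1 and 714 without P replicate 1, and the lower genes 1046 without P replicate 2. Of 26 lists 8 passed, and with an estimated correlation none did by camera, 1 having an unadjusted p under 0.05. The hypoxia list did not pass (adjusted p = 0.876), with a median of -0.02 and a test that pointed up. The medians of all passing lists in the 3 comparisons had the same sign under both other scalings, but with equal nuclear totals those of nuclear-encoded oxidative phosphorylation moved from -0.51 to -0.32 in P and from -0.25 to -0.04 in Y, and those of hypoxia from -0.29 to -0.11 and from -0.41 to -0.19.

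The effects of P and Y against CK were then compared across genes, which are not independent replicates. The log2 fold changes correlated with r = 0.832, where simulated unchanged groups sharing the 3 controls gave a mean of 0.4995 and at most 0.544. With no control in both comparisons r lay between 0.747 and 0.776. Genes higher in both treatments numbered 2050 and genes lower in both 1915, where independent lists would give 768 and 565. The shared controls can raise such counts. In the simulations of unchanged groups at most 0 genes were called in both. With no changed gene the adjustment leaves almost no calls in either comparison. That 0 therefore cannot show how far the shared controls raised the real counts. Of 4045 genes called in both, 67.0% had the larger effect in P. Equal signs, at 98.0%, do not by themselves show a common effect. Shared controls alone gave 98.7%, among a mean of 137 simulated genes at the looser threshold of an unadjusted p under 0.05 in both. Among 1008 of the called genes with equal signs that also differed between Y and P, 868 had the larger effect in P. PLIN2 was such a gene, at 18.5 ± 2.08 in CK, 58.9 ± 6.55 in Y and 288 ± 22.8 in P.

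**Figure D4:**
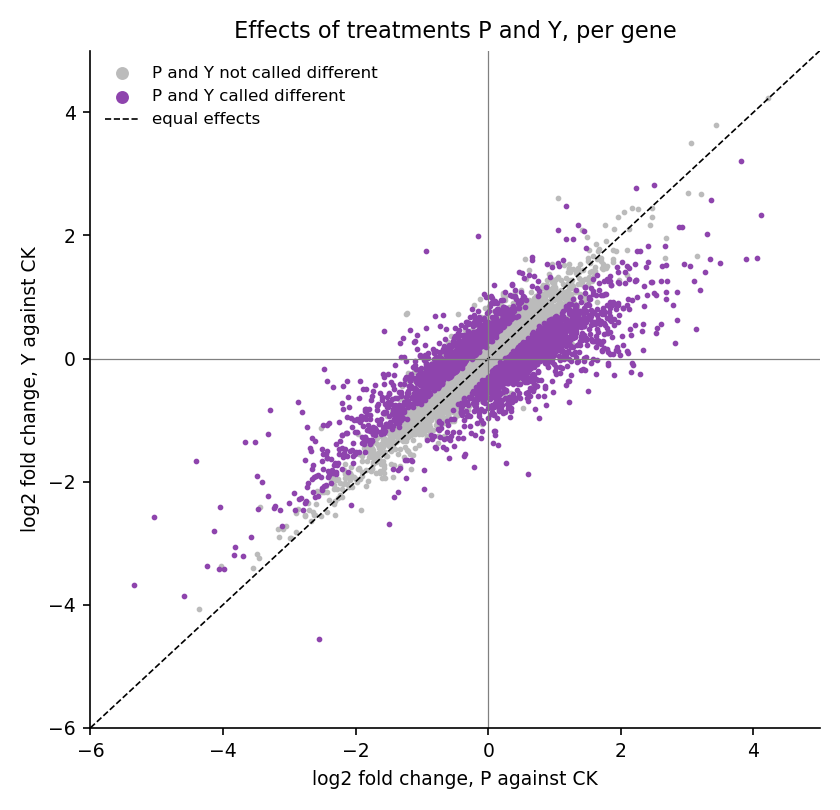
Log2 fold change against CK in P (horizontal axis) and in Y (vertical axis), with a point for each of the 11958 tested genes. Coloured genes were called different between Y and P, the dashed line marks equal effects, and r across genes is 0.832.

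Markers of other cell types were measured as well. Fibroblast markers reached at most 0.714 FPKM (COL1A1) and endothelial markers at most 0.101 (PECAM1), so none of them was tested. Of 9 immune cell markers 2 were above the filter, with a highest value of 10.4 for CD68, and they moved in opposite directions. CD68 was 1.53 ± 0.334 in CK, 7.69 ± 2.38 in P and 3.35 ± 0.678 in Y (log2 fold change 1.75 in P and 0.78 in Y), and CD14 was 4.201 ± 0.585, 0.374 ± 0.189 and 1.70 ± 0.183 (-1.92 and -0.94), all called.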

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

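The tests of a common loss of RNA with short or absent poly(A) tails and of the shared controls, together with both added scalings, the histone set and the opposite genes, were chosen only after the results they concern were seen.

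Mitochondrially encoded mRNAs fell in P (median log2 fold change -2.13) and were higher in Y than in P (median difference 1.49, camera adjusted p = 7.91e-12, and adjusted p = 0.581 with an estimated correlation). A scaling artefact is argued against by their median in P after rescaling, which was -1.94 at its highest, and a loss of short transcripts by the -0.0945 median of 1812 nuclear genes that are as short as the longest of them and as abundant, and by the -0.20 median of the 650 no longer than 784 bases, the median length of the mitochondrial transcripts. A common loss of RNA with short or no tails was predicted to move histone mRNAs, which have none, at least as much between Y and P. They differed by 1.07 less on the log2 scale (-1.07, 95% interval -1.71 to -0.49 on resampling the genes of each set). That interval takes the genes as independent and does not cover the spread between libraries. Between single libraries the histone median minus the mitochondrial one was negative in all 9 pairs of a Y and a P library, from -1.83 to -0.60. Each library serves in several pairs, so the pairs are not independent. Without Y replicate 3 the difference was -0.78. These values cannot decide on such a loss, because the way mRNA was selected is not known. Histone mRNAs can also change with the share of cells copying DNA. Of 58 histone genes 26 were higher in Y than in P and 1 lower (median 0.42), so such a loss stays open. For the fall in P against CK such a loss stays open, as histone mRNAs fell there too (median -2.44). An effect of the treatments on mitochondrial RNA stays open as a hypothesis.

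Clustered histone and DNA replication genes fell in both treatments: 54 of 58 tested histone genes fell in P (median -2.44), and 53 fell and 1 rose in Y (-2.21). Scaling is argued against by the DNA replication median, which was -1.56 at its highest with median-ratio scaling and -1.32 with equal nuclear totals. For the histone genes weaker recovery of RNA without poly(A) tails and a lower share of cells copying DNA were not told apart by the 6 histone genes with tails. Their median was -0.41 in P and -0.27 in Y, which both explanations allow. Weaker recovery of RNA without tails would not account for the DNA replication genes, whose mRNAs have tails. All 23 of them fell in P (median -1.65) and in Y (median -1.53). Reads shared among near-identical copies leave open which histone genes fell. A change in cell division under the treatments stays open as a hypothesis that expression values alone do not test.

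The effects of P and Y went together across genes (r = 0.832). Independent spread between the shared control libraries is argued against as the whole cause. The covariance of the fold changes was 0.342, and at most 0.0135 in simulations of unchanged groups with the same controls. With the controls split, 1 for one comparison and 2 for the other, the covariance was between 0.319 and 0.334 over the 6 splits, so little of it came from using the same libraries. A common response to both exposures stays open as a hypothesis.

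Other lists that passed between Y and P at the preset correlation had the median differences below, Y minus P, and none of them passed with an estimated correlation (adjusted p from 0.160 to 0.618). The NF-kB inflammatory median was -0.90 (17 of 21 genes lower), immediate early -0.85 (9 of 15), cholesterol synthesis -0.33 (10 of 23) and mesenchymal -0.30 (8 of 18). The mitosis median was 0.32 (7 of 20 genes higher), nuclear-encoded oxidative phosphorylation 0.18 (4 of 23) and DNA replication 0.13 (4 of 23). In 80 genes the effects of P and Y had opposite signs, with both effects and their difference past the threshold.

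Each comparison allows 10 splits of its 6 libraries, too few for a share under 0.05. Every other split mixes libraries of both groups, so a real difference adds to the spread and lowers the count of genes called. Part of that difference also stays between the mixed groups. The counts of the other splits therefore do not show what unchanged groups would give. The real split called 6244 genes in P against CK, 5083 in Y against CK and 2737 in Y against P, and the highest count in another split was 1, 2 and 2, so that 1 of the 10 splits gave as many each time. For gene lists at the preset correlation, the real split gave 10, 10 and 8 and the highest other split 9, 10 and 7. As many lists as in the real split came from 1, 3 and 1 of the 10 splits.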

How the results depend on the processing

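Both added scalings, the filter at 5 FPKM and the split of the controls were chosen only after the data were seen. Tests and scalings that need read counts, and a filter at 10 reads, were not run because the table analysed holds FPKM. With a log2 fold change of at least 1 required, the counts of higher and lower genes were 656 and 754 in P, 271 and 560 in Y, and 91 and 236 in Y against P, because fewer genes meet both criteria. After rescaling nuclear genes to equal totals, 4493 genes were higher and 1551 lower in Y, since that scaling adds to the fold change of every nuclear gene, and FKBP5 in Y turned to 0.12 (adjusted p = 0.349). With an estimated correlation 0 lists passed in P, 0 in Y and 0 in Y against P by camera. The lowest adjusted p-values by camera were 0.234, 0.198 and 0.160, with 4, 5 and 1 lists under 0.05 before adjustment. All 28 list calls were thus lost. How much of that loss came from genes that vary together was not tested. On leaving out each library in turn, genes higher in Y than P ranged from 702 (without Y replicate 1) to 1094, with 714 without P replicate 1, and genes lower from 1046 (without P replicate 2) to 1737, and the cause was not tested. TSC22D3 in Y ranged from -0.075 (without Y replicate 1) to 0.31, and did not pass. The correlation of the P and Y effects ranged from 0.814 to 0.839, and was 0.747 at its lowest with the controls split between the comparisons, as each effect then rests on fewer controls and none is shared. Of 2946 such values of called genes 94 lost their call, and 1 of 3000 values of named genes reversed, and of 252 such list values 11 lost theirs. Median-ratio scaling ended 1 of 28 list calls and 4 of 332 gene calls, and no filter on low values ended 8 of 332. The simulated test, with 3 libraries per group and few changed genes, recovered 28.4% of 67 changes of 0.5. No other group size was simulated, and few changed genes make the adjustment stricter than in the real data. Smaller changes were called there, such as that of ATP2B1 in P (0.22, limma adjusted p = 0.0287). Genes near 1 FPKM rest on about 48.9 to 57.2 implied fragments per 2000 bases.

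Replicate numbers did not pair the libraries: residual correlations of libraries with the same number lay between -0.15 and 0.07, and 1 of 9 libraries was closest to its own number. For libraries with other numbers they lay between -0.18 and 0.20, the highest being that of P replicate 1 and Y replicate 3. A structure shared across groups under other numbers was not tested. With replicate as a block, the counts of higher and lower genes were 3253 and 2633 in P, 2354 and 2231 in Y, and 905 and 1318 in Y against P, 11 of 332 calls of named genes ended, and 10, 10 and 8 lists passed.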

Other observations

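The genes in this part were chosen after their values were seen. Some genes moved in opposite directions under the treatments (FPKM means ± SD, n = 3). SLITRK6, a transmembrane protein, went from 6.03 ± 0.396 in CK to 1.37 ± 0.130 in P (log2 fold change -1.57, SE 0.09, adjusted p = 3.94e-07) and 8.53 ± 0.176 in Y (0.44, SE 0.09, adjusted p = 0.00275). FTL, the ferritin light chain that stores iron, went from 2817 ± 87.3 to 3560 ± 26.4 in P (0.34, SE 0.09, adjusted p = 0.0114) and 1780 ± 25.1 in Y (-0.66, SE 0.09, adjusted p = 3.53e-04). HAS3, a hyaluronan synthase, went from 3.18 ± 0.2505 to 10.9 ± 1.51 in P (1.498, SE 0.11, adjusted p = 3.27e-06) and 1.91 ± 0.176 in Y (-0.52, SE 0.11, adjusted p = 0.00457). TNFAIP3, an inhibitor of NF-kB signalling, went from 7.83 ± 0.962 to 14.9 ± 1.21 in P (0.85, SE 0.13, adjusted p = 3.59e-04) and 4.78 ± 0.833 in Y (-0.62, SE 0.13, adjusted p = 0.00368).

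The 3 fibrinogen genes fell together in Y too, to 7.84 ± 0.316 for FGA (-2.58, SE 0.12, adjusted p = 5.54e-07), 4.09 ± 0.220 for FGB (-2.79, SE 0.18, adjusted p = 2.56e-06) and 7.06 ± 0.865 for FGG (-2.42, SE 0.13, adjusted p = 8.66e-07).

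Libraries of a group correlated with r between 0.977 and 0.985 across genes, and libraries of different groups with r between 0.881 and 0.959. The first principal component held 64.0% of the variance and the second 15.2%. Log2 fold changes had a Spearman rho across genes with transcript length of 0.131 in P and 0.124 in Y. The authors' deposited comparison called 1977 genes higher and 2364 lower in P, 884 and 1685 in Y, and 401 and 812 in Y against P. Of the authors' calls among the genes tested here, 96.4%, 96.2% and 96.0% were also called here with the same sign, which are 3557 of the 6244 calls made here, 2108 of 5083 and 953 of 2737. Some genes named above as called did not pass in the authors' unnamed test. Among them were AHR in P (adjusted p = 0.0978), and AHR (0.441), CYP1B1 (0.642) and ARPIN-AP3S2 (0.165) in Y against P.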
